A study of Mus musculus with 6 samples.

How the data were processed

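Single-cell RNA was measured in lungs of C57BL/6J mice in 6 groups of 1 library each. Per the labels, libraries used the 10x 3' chemistry, and CD45-positive and CD45-negative fractions, prepared by different digestions, were enriched, tagged with hashtags and pooled. The deposited files hold raw counts: UMIs per gene and cell barcode for 32285 genes, which the authors made with Cell Ranger 6.0.1 on the mm10 genome according to the submitters' processing notes. Hashtag counts were not used here, so a planned comparison of hashtags with cell classes was not made. Gene positions come from the GENCODE mouse annotation, release M21, of that genome build. Values are sums of whole UMI counts, and every interval and floor covers counting error only.

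Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, 40307 of 42475. Scrublet, run in each library with an expected doublet rate of 0.08 and 30 components, called 2175 doublets (238 to 557 per library), and 38132 cells were kept. UMI counts were scaled to 10000 per cell and log-transformed. Cells of all libraries were clustered together with the Leiden method on 40 principal components of 3000 variable genes (20 neighbors, resolution 3), and again within each of 4 families (T, NK and innate lymphoid, dendritic, mesenchymal and epithelial cells) on 2000 variable genes (resolution 1.5), with no correction between libraries. This gave 113 clusters, of which 11 stayed unnamed. A cluster was named for the class of 34 marker classes with the highest mean marker score, where at least 3 markers of that class were detected (in at least 20% of cells and at least 2-fold above the mean of clusters of other families), the leading 10 genes did not go against the name, and the cluster was not under 1/3 of its libraries' depth with no marker among those genes. These thresholds, and the rule that 5 markers of another family leave a cluster unnamed, were set after the data were seen, and the unnamed share of each library is given with the class shares. Within a family, a cluster took a class name where its score led the next class by 0.2 and its leading genes held no more markers of another class than of its own. The others were kept at the level of the family, and monocyte with interstitial macrophage clusters, and alveolar with adventitial fibroblast clusters, were also joined. The joined monocyte class includes classical monocyte-like cells. Clusters 91 and 108 held 1 more marker of another class than of their own among the leading 10 genes against all clusters, but not against clusters of other families. They were kept, and values without them are given for some of the results that include them.

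Shares are percentages of the named hematopoietic or non-hematopoietic cells of a library with exact Clopper-Pearson 95% intervals. For gene levels, UMIs were summed per library and class, in classes with at least 30 cells in both libraries, and divided by the class total as CPM with exact Poisson 95% intervals. Ratios of gene levels have exact conditional binomial 95% intervals. Ratios of shares have 95% intervals from a normal approximation on the log scale. A gene was measured where both libraries together held at least 20 UMIs and the higher CPM was at least 20. A ratio against 0 counts uses a floor of 3 counts per library and is a lower bound. Adventitial fibroblast-like, CD4 T-like and cDC2-like cells fell under 30 cells in some libraries and are not compared there.

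Before the data were examined, 7 comparisons, the cell type markers, 19 gene lists, the rule for named genes and the alternative settings were fixed. The lists cover the interferon-gamma response, type I interferon response, MHC class II, MHC class I with the immunoproteasome, the IL-4 and IL-13 (STAT6) response, type 2 stromal cytokines and eotaxins, type 2, type 1 and type 17 lymphocyte effectors, neutrophil-attracting cytokines, monocyte- and lymphocyte-attracting chemokines, endothelial adhesion, extracellular matrix, mucous and goblet genes, immunoglobulin constant regions, proliferation, immediate early genes, glycolysis and hypoxia, and free-RNA tracers. For each list with at least 4 measured members the members at least 2-fold higher, at least 2-fold lower and between are counted, and the median log2 ratio is placed among 10000 random lists matched on expression in 20 bins. Counts under 3 are set to 3 in these medians. Counts and percentiles describe these libraries only. Named genes are, for each described list and class, up to 4 members with the largest ratio whose interval excludes 1, and by size the 2 highest and 2 lowest genes in adventitial fibroblast-like, general capillary endothelium-like, classical monocyte-like, alveolar macrophage-like, cDC2-like and CD4 T-like cells. 1 gene that this rule gave is not reported here. Which list and class pairs are described was chosen after the list medians were seen. The 12 main results were chosen after their values were seen and before any alternative was run. Intervals of list medians are order statistics over the list's members.

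The share of free RNA in each library, 3.18% to 6.77%, was estimated as the median over 4 tracer genes in 7 classes that lack them (6 in papain+CpG day 3 and papain+CpG recall, without CD4 T-like cells). The tracers disagreed: Scgb1a1 read 30.6% to 72.6% of its library level at papain day 3 and 80.5% to 146% at papain+CpG recall, where the other 3 read 1.07% to 5.64% and 2.59% to 7.38%. Without Scgb1a1 the shares were 2.33% to 6.16%. Lists with opposite directions in related comparisons were sought by their intervals. The rule gave 49 pairs, 45 without the single fibroblast classes, of which 18 had both medians past 0.5 and are listed in the closing section. The size limit and the removal of the single fibroblast classes were chosen after the data were seen. No model was fitted and no p-value was computed, since each group holds 1 library.

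Alternatives were TMM factors, a total without mitochondrial, ribosomal and hemoglobin genes, doublets kept, a lower clustering resolution of 1.5, each gene centred within libraries, stricter cell filters (at least 500 genes and at most 10% mitochondrial UMIs), cells thinned to 1000 UMIs (with 153, 759, 196, 159, 261 and 530 shallower cells left out of the 6 libraries), free RNA subtracted, a lower limit for measured genes (5 UMIs together), 0.5 added to counts and shares of all kept cells. Leaving out clusters 91 and 108, and counting unnamed cells as hematopoietic, were added after the data were seen.

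The steps from sums to ratios and list percentiles were tested on simulated data for papain+CpG against papain after recall in general capillary endothelium-like cells, with 200 changed genes. Median log2 ratios of 0.99, 1.97, −1.05 and −2.02 were recovered for true values of 0.97, 1.97, −1.03 and −2.03, and 95.3% to 98% of intervals held the true ratio. Counts were drawn from the Poisson model that the intervals assume, so this coverage checks the computation only. Clumping of UMIs in single cells, free RNA and variation between libraries were not simulated, and intervals can be too narrow where they occur. A list of 15 doubled genes reached percentile 100, and 20 lists of unchanged genes ran from 2.40 to 92.6. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9 and edgeR 4.0.16 for TMM factors.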

Results

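The series measured single-cell gene expression in whole lungs of female C57BL/6J mice after exposure to papain, a cysteine protease used as an allergen, with or without CpG, a DNA ligand of the innate receptor TLR9. Per the labels, mice received 20 µg papain, or 20 µg papain with 8 µg CpG, on days 1 to 3. Lungs were taken at day 3, at day 42 without a further exposure, or at day 42 after a recall exposure at day 41. The 6 groups held 1 library each, so no difference below has a replicate check and no test was made. Intervals in brackets are 95% counting intervals and cover counting error only. The libraries held 2536 to 10738 barcodes and 28663717 to 66876060 UMIs (unique molecular identifiers). After filters and removal of called doublets, 5065 cells remained in papain day 3, 9844 in papain+CpG day 3, 8788 in papain day 42, 5955 in papain+CpG day 42, 6335 in papain recall and 2145 in papain+CpG recall. Median UMIs per kept cell ran from 4151.5 in papain day 42 to 5642 in papain+CpG recall, where shallow unnamed cells described below are included. Within classes, depth differed more. Alveolar macrophage-like cells had medians of 35354 UMIs in papain+CpG recall, 21247 in papain recall and 12047 in papain+CpG day 42. B-like cells had 7004, 4103 and 3261.5 in the same libraries. The label of the papain+CpG recall sample can be read as giving CpG again at recall, while the series design names a secondary challenge with papain, and the files do not settle which is right.

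Cells were grouped by marker genes into classes named for the cell type they resemble. Hematopoietic (CD45-positive) and other cells were prepared by different digestions, enriched and pooled, so each class is given as a share of the named cells of its own compartment. The enrichment and digestion steps can set these shares. A rise in the share of any class also lowers those of the others in its compartment. A class called monocyte or interstitial macrophage joined all such clusters, because day 3 of papain+CpG filled clusters of its own, and fibroblasts were joined likewise. No cluster met the markers of eosinophils. Cells of unnamed clusters made up 1.58%, 1.58%, 1.41%, 1.36%, 3.96% and 25.4% of the kept cells of the 6 libraries in the order above. In papain+CpG recall most of them, 519 cells, lay in cluster 29, whose median was 586 UMIs over all its cells.

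The comparison of papain+CpG with papain at day 3 addressed the acute effect of CpG on the response to the allergen. Monocyte or interstitial macrophage-like cells made up 58.5% (57.3 to 59.6) of hematopoietic cells with CpG and 11.7% (10.5 to 13.1) without it, a 4.98-fold higher share (4.47 to 5.56). Plasmacytoid dendritic cell-like cells, known producers of type I interferon, held 2.18% against 0.562%, and NK-like cells held 4.88% against 2.89%. Alveolar macrophage-like cells were 7.55-fold lower in share (6.68 to 8.54), at 4.51% against 34.1%. ILC2-like cells (group 2 innate lymphoid cells, a source of IL-5 and IL-13) were lower too, at 5 of 6696 cells against 35 of 2489. CD4 T-like cells were 15.4-fold lower, cDC2-like dendritic cells 8.35-fold lower and gamma-delta T-like cells 5.28-fold lower. The CD4 T-like fold rests on 29 cells with CpG, where 55 further cells were named only to the T, NK and innate lymphoid family. The higher monocyte or interstitial macrophage share by itself lowers the shares of all other classes, so these folds do not measure losses of cells. The log2 ratio of the monocyte or interstitial macrophage share was 2.32, and 3.78 when each gene was centred within libraries before clustering.

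**Figure D1:**
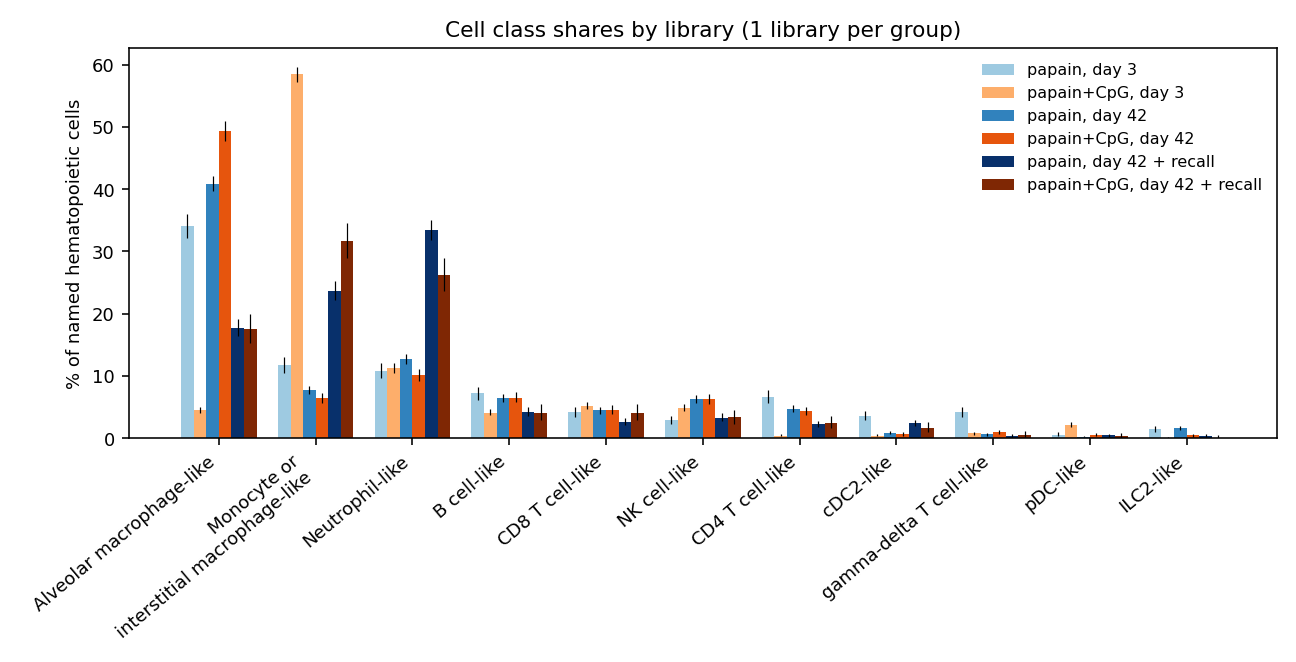
Bars give each class as a percentage of the named hematopoietic cells of its library, with exact binomial 95% intervals over cells, for the 6 libraries of 1 replicate each. Monocyte or interstitial macrophage-like cells stand at 58.5% in papain+CpG day 3, and neutrophil-like cells at 33.4% and 26.2% after recall against 12.7% and 10.1% without it.

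In alveolar macrophage-like cells at day 3, all 22 measured interferon-gamma response genes were at least 2-fold higher with CpG, with a median log2 ratio of 4.59 (percentile 100 among random lists matched on expression). Cxcl9, a chemokine for activated T cells (ENSMUSG00000029417, mm10 chromosome 5, 92321347 to 92328079, minus strand, protein-coding), had 1663 CPM (counts scaled to a common class total) against 2.85, 583-fold higher (427 to 816). Serpina3g, a serine protease inhibitor, had 303 against 1.64 CPM, and Iigp1, an interferon-inducible GTPase, 284 against 1.93. Nos2, the inducible nitric oxide synthase, had 139 CPM with CpG and 0 counts without it, at least 648-fold higher against a floor of 3 counts per library. Saa3, an acute-phase protein, had 1730 (1687 to 1774) against 1.93 CPM. Its level in capillary cells of the same library, given below, lay near the free-RNA estimate. Part of the 1730 CPM may therefore be free RNA, and this was not tested. The list of responses to IL-4 and IL-13 through STAT6 moved the other way, with 6 of 10 measured genes at least 2-fold lower, 4 between and a median of −1.62 (percentile 0). Ccl17, a chemokine for type 2 T helper cells (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036, plus strand), had 2.00 CPM against 243, a 121-fold lower level (58.7 to 302). Chil4, a chitinase-like protein, and Fbp1, the gluconeogenic fructose bisphosphatase (ENSMUSG00000069805, chromosome 13, 62864753 to 62888282, minus strand), had 0 counts with CpG, at least 105-fold and at least 115-fold lower than 90.1 and 98.9 CPM. Arg1, an arginase that breaks down arginine, had 15.7 against 71.1 CPM. Different clusters held these cells, with 81.5% in cluster 41 with CpG and clusters 7 and 10 leading without it.

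At day 3, monocyte or interstitial macrophage-like cells had all 18 measured type I interferon response genes at least 2-fold higher with CpG (median log2 ratio 3.48, percentile 100). Isg15, an interferon-induced ubiquitin-like modifier, had 2237 against 39.6 CPM, and Ifit2, an interferon-induced RNA-binding protein, 226 against 6.93. Chemokines that attract monocytes and lymphocytes were at least 2-fold higher in 8 of 8 measured (median 3.34, percentile 100), with Cxcl9 at 673 against 3.18 CPM, Ccl12 at 817 against 4.62 and Ccl5 at 4646 against 396. Of 12 measured STAT6 response genes, 10 were at least 2-fold lower, 1 was higher and 1 lay between (median −2.98, percentile 0). Retnla, a secreted product of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand), had 4.50 CPM against 1352, 300.4-fold lower (254 to 358). Ccl24, an eosinophil-attracting chemokine (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049, minus strand), had 2.14 against 434 CPM. In classical monocyte-like cells alone, 3 of 6 measured STAT6 genes were at least 2-fold higher, 2 lower and 1 between (median 0.94, percentile 96.4). In that class Cxcl10 had 3006 against 7.09 CPM, the growth factor receptor Igf1r had 1.69 against 26.6 CPM, and S1pr5, a receptor for sphingosine phosphate, had 2.17 against 24.8. Clusters 38 and 40 led the joined class with CpG, and clusters 8 and 4 without it.

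Structural cells carried the interferon pattern as well at day 3. General capillary endothelium-like cells had 22 of 22 interferon-gamma response genes (median 3.08, percentile 100) and 7 of 7 MHC class II genes (median 3.17, percentile 100) at least 2-fold higher with CpG. Cd74, the MHC class II invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, plus strand), had 4223 CPM against 132, 32.0-fold higher (28.8 to 35.6), and the class II chain H2-Ab1 had 1382 against 152. The adhesion list had 3 of 4 measured genes at least 2-fold higher and 1 between (median 1.71, percentile 99.8), with the leukocyte adhesion molecules Vcam1 at 85.6 against 3.62 CPM and Icam1 at 364 against 74.9. Cyp26b1, which degrades retinoic acid (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908, minus strand), had 11.4 CPM against 3348, 293-fold lower (212 to 416), and the apelin receptor gene Aplnr had 8.97 against 250.4. Saa3 in these cells, 701 against 0 CPM, stood at 7.78% of the whole library's level, near the 6.77% of free RNA estimated for papain+CpG day 3. Cluster 1 held most of the class with CpG and cluster 12 without it.

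Fibroblast-like cells at day 3 had 10 of 10 measured chemokines at least 2-fold higher with CpG (median 4.47, percentile 100, and 4.54 without cluster 91). Cxcl9 had 859 CPM against 1 count (2090.5-fold, 374 to 82640.0), Cxcl10 had 958 against 2.05 CPM, and Ccl7, a monocyte chemokine, had 258 against 9.04. The matrix list had 7 of 15 measured genes at least 2-fold lower, 1 higher and 7 between (median −0.99, percentile 0, and −0.79 without cluster 91). Postn, the matrix protein periostin, had 3 counts (2.23 CPM) against 77.2 CPM, 34.6-fold lower (11.6 to 169), while Timp1, an inhibitor of matrix metalloproteases, had 2121 against 360.0. Cluster 91, with 204 cells of papain+CpG day 3, had 1 more marker of another class than of its own among its leading genes when set against all clusters, and values without it are given for that reason. It held 78.2% of fibroblast-like cells with CpG, while cluster 76 held 50.7% without it. A different mix of alveolar and adventitial fibroblasts could change these values, and this was not tested. AT2-like alveolar epithelial cells had 13 of 13 genes of MHC class I and the immunoproteasome at least 2-fold higher (median 2.59, percentile 100), with the class I gene H2-Q7 at 1275 against 49.3 CPM and the proteasome subunit Psmb8 at 1354 against 60.8. Lcn2, an iron-siderophore-binding defence protein, had 21799 against 2177 CPM, within a neutrophil-attracting list of 5 genes higher and 2 between (median 2.41, percentile 100). Proliferation genes were lower in AT2-like cells in 8 of 8 (median −4.27, percentile 0), with Mki67 at 2.81 against 88.5 CPM and Cenpf at 1.57 against 92.7. Without CpG the 686 UMIs of Mki67 lay in 53 of 491 cells (10.8%), while 4.47% of B-like cells held it at lower depth (medians of 3543 and 15286 UMIs). Clusters 104 and 103 led AT2-like cells with CpG, and clusters 94 and 95 without it.

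Among lymphocytes at day 3, CD8 T-like cells had 9 of 15 type 1 and cytotoxic effector genes at least 2-fold higher with CpG and 6 between (median 1.31, percentile 100). Xcl1, a chemokine for cross-presenting dendritic cells, had 415 against 28.2 CPM, Gzma 761 against 68.6 and Gzmb, a cytotoxic granule protease, 346 against 34.3. NK-like cells had 6 of 15 higher, 2 lower and 7 between (median 0.40, percentile 84.8), with Xcl1 at 2708 against 133 CPM and Ifng, which encodes interferon-gamma, at 827 (783 to 873) against 159 (115 to 214). Gamma-delta T-like cells had 1 of 5 type 17 genes at least 2-fold lower and 4 between (median −0.83, percentile 0.835), with the IL-23 receptor gene Il23r at 7 counts (35.8 CPM) against 85.7 CPM. Clusters 54 and 51 led CD8 T-like cells with CpG against 47 and 50 without it, and NK-like cells lay mostly in cluster 56 against 45. Over the 15 classes with enough cells, the interferon-gamma list was above 0 in 15, from 0.88 in migratory dendritic cell-like cells to 4.80 in AT2-like cells, and the STAT6 list was below 0 in 15, with classical monocyte-like cells counted inside the joined class. Taken alone, classical monocyte-like cells had a STAT6 median above 0. The STAT6 list was drawn up for myeloid cells, so here and below its values in other classes need not reflect a STAT6 response there. The free-RNA tracer list, transcripts of abundant lung cell types read outside their own type, was above 0 in 12 of 15 (median 0.47).

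**Figure D2:**
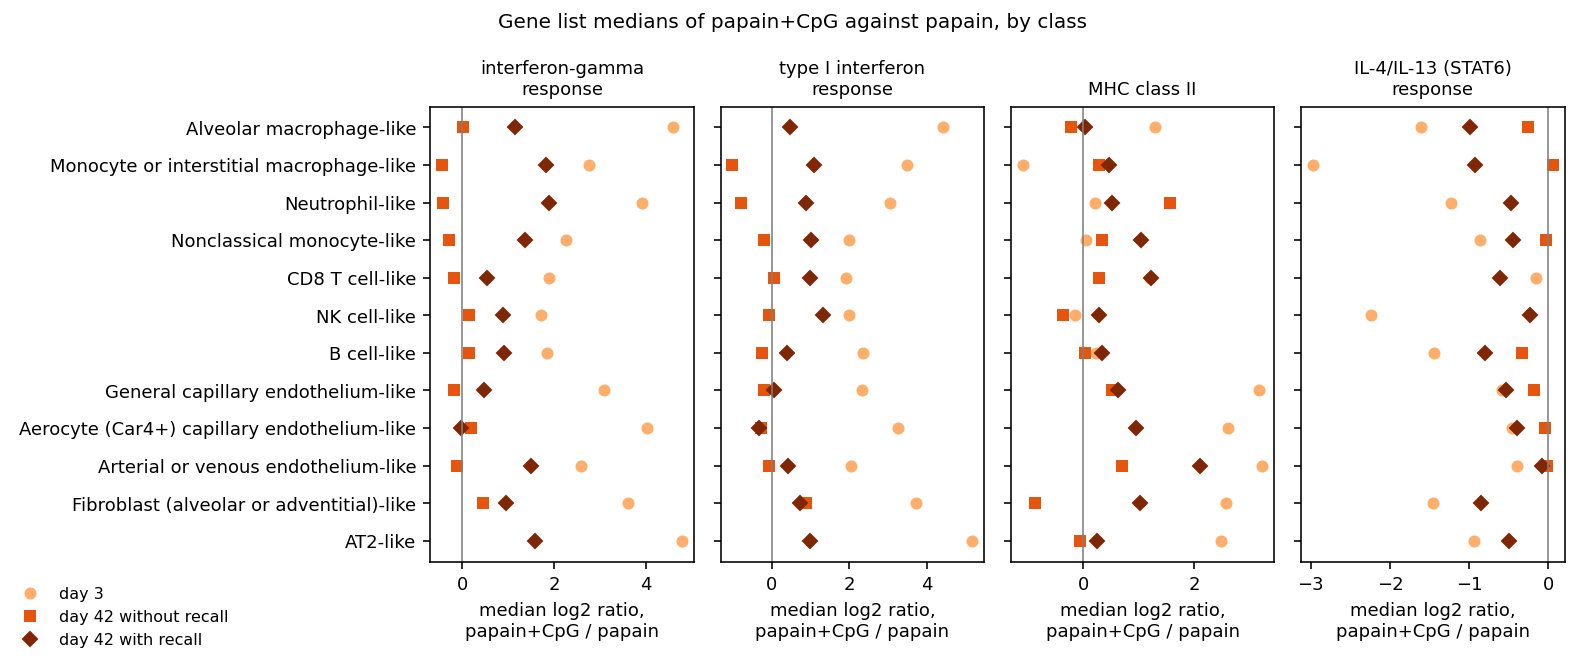
Points give the median log2 ratio of 4 gene lists in papain+CpG against papain by class, at day 3, at day 42 without recall and at day 42 with recall, each from 1 library per group, with no point where too few genes or cells were measured. The interferon-gamma median of alveolar macrophage-like cells is 4.59 at day 3 and 1.15 with recall, and the STAT6 medians are −1.62 and −0.99.

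The comparison at day 42 without recall addressed what remained of the first exposure after 6 weeks. The interferon-gamma list was above 0 in 9 of 16 classes, with a median over classes of 0.06 against 2.77 at day 3. The STAT6 list was still below 0 in 9 of 10 classes, with a median of −0.16 against −1.09 at day 3. ILC2-like cells were 3.80-fold lower in share with CpG (2.28 to 6.34), at 0.441% against 1.68% of hematopoietic cells. CD4 T-like cells were close in share, at 4.33% (3.71 to 5.02) against 4.76% (4.24 to 5.33). In general capillary endothelium-like cells, Cd74 had 1349.9 CPM against 622, 2.17-fold higher (2.03 to 2.32), and H2-DMa and H2-DMb1, which load class II molecules, were 1.92-fold (1.58 to 2.33) and 1.82-fold higher (1.49 to 2.22). That list of 7 MHC class II genes had 1 at least 2-fold higher and 6 between (median 0.52, percentile 100), while 17 interferon-gamma genes all lay between (median −0.17, percentile 0.99), with Gbp6 at 34.9 against 63.4 CPM. Arterial or venous endothelium-like cells had 4 of 7 adhesion genes at least 2-fold lower with CpG and 3 between (median −1.12, percentile 0). Sele, which encodes E-selectin (ENSMUSG00000026582, chromosome 1, 164048234 to 164057677, plus strand), had 12.2 CPM against 104, 8.52-fold lower (4.52 to 17.8), Selp, for P-selectin, had 57.7 against 135, and Vcam1 had 323 against 704. Clusters 20 and 0 held the arterial or venous class in all libraries, at different shares, with 32.4% in cluster 0 with CpG and 44.2% without it. Clusters 2 and 16 led the capillary class in both groups.

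In alveolar macrophage-like cells at day 42, 2 of 8 STAT6 response genes were at least 2-fold lower with CpG and 6 lay between (median −0.26, percentile 0.03). Arg1 had 0.641 CPM against 25.6, 39.9-fold lower (24.0 to 71.7), and Ccl17 had 3.20 against 27.6. Fbp1 had 0 UMIs in 1903 cells with CpG, which allows up to 0.128 CPM, against 34.7 CPM in 2466 cells without it, at least 271-fold lower. That level came from 112 of the 2466 cells (4.54%, and 0.258% of B-like cells at lower depth), and 697 of their 957 UMIs lay in cluster 7, which held 72 cells of papain day 42 and 9 of papain+CpG day 42. Mmp12, a macrophage elastase, had 9.61 against 73.9 CPM. Without CpG the UMIs of Arg1, Ccl17 and Mmp12 lay in 7.50%, 5.07% and 11.2% of these cells. With CpG the shares were 0.525%, 3.36% and 4.68%, and 0.397%, 1.59% and 0.794% of B-like cells held these genes at lower depth (medians of 3261.5 and 12047 UMIs). Apoc1, an apolipoprotein, was 2.28-fold higher (2.02 to 2.57), and the neutrophil-attracting list held 4 genes, all between (median 0.36, percentile 100), among them Cxcl2 at 624 against 377 CPM. Classical monocyte-like cells had Cxcl9 at 45.6 CPM against 4 counts (2.05 CPM), 22.2-fold higher (8.08 to 85.2). By contrast with day 3, monocyte or interstitial macrophage-like cells had 9 of 17 type I interferon genes at least 2-fold lower with CpG and 8 between (median −1.01, percentile 0), with Isg15 at 119 against 294 CPM and Oasl1 at 5.45 against 20.9. In classical monocyte-like cells alone all 16 measured genes of that list lay between (median −0.44, percentile 0), and the make-up of the joined class differed. Fibroblast-like cells had 4 of 9 of these genes at least 2-fold higher and 5 between (median 0.88, percentile 100), with Ifit1 at 30.9 against 4.28 CPM and Isg15 at 35.7 against 15.5. Clusters 10 and 11 led alveolar macrophage-like cells with CpG against 10 and 9 without it, cluster 4 led the joined monocyte class in both at different shares (47.6% with CpG and 69.3% without it, with 39.6% and 16.1% in cluster 8), and clusters 74 and 78 led fibroblast-like cells with CpG against 78 and 73.

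CD4 T-like cells at day 42 had 4 of 5 measured type 2 effector genes at least 2-fold lower with CpG and 1 between (median −1.61, percentile 0). Areg, an epidermal growth factor receptor ligand, had 15.8 CPM (8.16 to 27.6) against 52.6 (39.6 to 68.5), and Il1rl1, the IL-33 receptor gene, 11.8 (5.42 to 22.5) against 30.6 (20.9 to 43.2). Of 7 type 1 and cytotoxic genes, 3 were at least 2-fold higher, 1 was lower and 3 lay between (median 0.99, percentile 100). Gzma, a granule protease, had 56.6 CPM against 3 counts (19.7-fold, 6.31 to 99.4), Ccl5 had 417 against 118 CPM, and Cxcr6, a chemokine receptor of tissue T cells, had 6.58 against 51.7. Areg, Il1rl1 and Cxcr6 are also in the fixed ILC2 marker list, and Gzma is in the NK list. ILC2-like cells were 3.80-fold lower in share in this comparison. A few such cells inside the CD4 T-like class could give these values, and this was not tested. With called doublets kept and cells clustered again, the type 1 median was −0.05 and the log2 ratio of Ccl5 was −0.05, against 1.83.

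The comparison of papain+CpG with papain after recall addressed whether the first exposure shaped the response to a second one. If CpG was given again at recall, as the label can be read, the values also hold the effect of that dose. The interferon-gamma and type I interferon lists were each above 0 in papain+CpG in 11 of 12 classes (medians over classes 1.06 and 0.82), the exception being aerocyte-like capillary cells at −0.02 and −0.33. The STAT6 list was below 0 in 12 of 12 (median −0.52), and the free-RNA tracer list was below 0 in 10 of 12 (median −0.22). Alveolar macrophage-like cells had 12 of 20 interferon-gamma genes at least 2-fold higher and 8 between (median 1.15, percentile 100), and 6 of 12 STAT6 genes at least 2-fold lower and 6 between (median −0.99, percentile 0). Iigp1 had 92.5 CPM against 8.34, 11.1-fold higher (9.05 to 13.7), and Cxcl9 261 against 28.7. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand) had 178 CPM against 1179, 6.62-fold lower (6.26 to 7.01), Pdcd1lg2, a ligand of the inhibitory receptor PD-1, had 26.0 against 162, and Fbp1 8.25 against 160.3. C5ar1, the receptor for complement C5a, had 62.6 against 6.52 CPM. Retnla, at 32.7 against 399.7 CPM, stood at 4.52% and 3.83% of the library levels, within reach of free RNA.

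After recall, monocyte or interstitial macrophage-like cells had 19 of 21 interferon-gamma genes at least 2-fold higher in papain+CpG and 2 between (median 1.82, percentile 100). Cxcl9 had 1252 CPM against 87.2, 14.4-fold higher (13.4 to 15.4), and Cxcl10 601 against 73.1. STAT6 response genes were at least 2-fold lower in 6 of 13 and between in 7 (median −0.92, percentile 0), with Arg1 at 986 against 4144 CPM, Ccl24 at 3181 against 10438 and the mannose receptor Mrc1 at 207 against 741. Neutrophil-like cells had 18 of 19 interferon-gamma genes higher and 1 between (median 1.90, percentile 100), among them the interferon-inducible GTPases Tgtp1 at 146 against 12.7 CPM and Gbp4 at 139.8 against 13.8. Classical monocyte-like cells had Ccl5 at 286 CPM against 4 counts (89.2-fold, 34.6 to 329). Classical monocyte-like cells held 9.86% against 4.16% of hematopoietic cells, 2.37-fold higher (1.86 to 3.02), and neutrophil-like cells 26.2% against 33.4%. The joined monocyte or interstitial macrophage share was 31.7% against 23.7% (log2 ratio 0.42), and that ratio turned to −0.07 when unnamed cells, 25.4% of papain+CpG recall, were counted as hematopoietic. Clusters 7 and 11 led alveolar macrophage-like cells in papain+CpG against 7 and 22 in papain, cluster 5 led the joined monocyte class and cluster 25 the neutrophils in both.

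Among structural cells after recall, fibroblast-like cells had 5 of 9 type 2 stromal genes at least 2-fold lower in papain+CpG, 1 higher and 3 between (median −1.16, percentile 0). The median was −1.67 without cluster 91. Ccl11, the chemokine eotaxin (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955, plus strand), had 140.3 CPM against 1909.5, 13.6-fold lower (11.4 to 16.3). Il33, an epithelial and stromal alarmin (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, plus strand), had 36.7 against 172 CPM in fibroblast-like cells and 715 against 2158 in AT2-like cells. Ccl11 and Il33 are also in the fixed marker list of adventitial fibroblasts, which are joined here with alveolar ones. A different mix of both between libraries could change these fibroblast values too, here and in every other comparison of fibroblast-like cells. This was not tested. AT2-like cells had 3 of 5 type 2 stromal genes at least 2-fold lower, 1 higher and 1 between (median −1.59, percentile 0, and −1.35 without cluster 108), and 11 of 13 interferon-gamma genes higher with 2 between (median 1.58, percentile 100, and 1.79 without cluster 108). The gene higher was Ccl24, at 13.7% and 2.42% of the library levels, and its log2 ratio turned to −2.30 with called doublets kept and cells clustered again. Immediate early and dissociation genes, which can mark tissue handling, were also higher in AT2-like cells of papain+CpG (median 1.08, percentile 100). Arterial or venous endothelium-like cells, 36 against 187 cells, had 4 of 7 adhesion genes lower, 1 higher and 2 between (median −1.66, percentile 0.01). Ackr1, a chemokine-binding receptor of venules (ENSMUSG00000037872, chromosome 1, 173331886 to 173333750, minus strand), had 0 counts against 451 CPM, at least 43.0-fold lower, and Selp had 391 against 1239. General capillary endothelium-like cells had 2 of 22 interferon-gamma genes at least 2-fold higher, 1 lower and 19 between (median 0.47, percentile 100), with Cxcl9 at 180.1 against 34.3 CPM and Serpina3g at 91.4 against 389. Their matrix list had 3 of 6 lower and 3 between (median −0.94, percentile 0), with the thrombospondin gene Thbs1 at 64.0 against 489 CPM, and Esm1, a marker of endothelial sprouting, had 43.9 against 5.30. CD8 T-like cells, 44 against 86, had 3 of 14 type 1 genes higher and 11 between (median 0.55, percentile 99.9), with the chemokine receptor Cxcr3 at 105 against 40.9 CPM. Clusters 81 and 79 led fibroblast-like cells in papain+CpG against 77 and 93 in papain, clusters 106 and 101 led AT2-like cells against 109 and 108, and cluster 13 led the capillary class in both. Cluster 0 held 41.7% of the arterial or venous class in papain+CpG and 48.1% in papain.

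Recall against no recall under papain addressed the response to a second encounter with the allergen. Neutrophil-like cells held 33.4% (31.8 to 35.0) of hematopoietic cells after recall and 12.7% (11.9 to 13.6) without it, 2.63-fold higher (2.42 to 2.85). The log2 ratio was 1.40, and 1.01 as a share of all kept cells. Monocyte or interstitial macrophage-like cells were 3.07-fold higher and cDC2-like cells 2.66-fold higher, while alveolar macrophage-like cells were 2.30-fold lower. AT2-like cells held 18.4% against 9.60% of non-hematopoietic cells (log2 ratio 0.94, and 0.45 without cluster 108). The STAT6 list was above 0 in 17 of 17 classes (median 2.12) and the interferon-gamma list in 16 of 17 (median 1.16). The free-RNA tracer list was above 0 in 16 of 17 (median 1.31).

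In alveolar macrophage-like cells, 8 of 12 STAT6 genes were at least 2-fold higher after papain recall and 4 between (median 2.48, percentile 100). Ccl24 had 2066 CPM against 6.24, 331-fold higher (285 to 387), Arg1 had 1179 against 25.6, and Ccl17 789 against 27.6. Interferon-gamma genes were at least 2-fold higher in 10 of 13 and between in 3 (median 2.30, percentile 100), with Serpina3g at 96.8 against 1.13 CPM and Socs1, an inhibitor of cytokine signalling, 17.8-fold higher (13.7 to 23.5). Fabp1, a fatty acid-binding protein, had 15.2 against 245 CPM, and C5ar1 had 6.52 against 108. In the joined class of monocyte or interstitial macrophage-like cells, 10 of 13 STAT6 genes were higher and 3 between (median 2.14, percentile 100), with Arg1 at 4144 CPM against 9.77, 424-fold higher (295 to 633), and Ccl24 at 10438 against 41.8. Neutrophil-like cells had 8 of 10 STAT6 genes higher and 2 between (median 4.45, percentile 100). Ccl24 and Retnla there stood at 24.1% and 8.15% of the library level, and Arg1 had 318 CPM against 0 counts, at least 161-fold higher. In cDC2-like cells the receptor gene Cd209e had 165 CPM against 2 counts (38.3-fold, 10.4 to 319), and the secreted-protein gene Mucl1 had 0 counts against 252 CPM, at least 83.0-fold lower. CD4 T-like cells, 74 against 287, had 4 of 6 type 2 effector genes higher and 2 between (median 1.23, percentile 100), with the IL-2 receptor gene Il2ra at 197 against 20.1 CPM and Areg at 276 against 52.6. Areg is also in the fixed ILC2 marker list. Clusters 7 and 22 led alveolar macrophage-like cells after recall against 10 and 9 without it, cluster 5 led the joined monocyte class against 4, cluster 25 led the neutrophils against 14, and clusters 64 and 60 led cDC2-like cells against 63 and 70. Cluster 64, with Cd209e among its leading genes, held 67.9% of cDC2-like cells after recall and none without it.

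Fibroblast-like cells after papain recall had 8 of 8 type 2 stromal genes at least 2-fold higher (median 3.85, percentile 100), with Ccl11 at 1909.5 CPM against 62.2, 30.7-fold higher (26.2 to 36.2), and Ccl7 at 211 against 7.77. Neutrophil-attracting and acute inflammatory genes were higher in 6 of 7 and between in 1 (median 3.42, percentile 100). Saa3 had 2218 CPM against 1 count (5706-fold, 1024 to 225428), Lcn2 had 718 against 4.28 CPM, and the neutrophil chemokine Cxcl5 had 215 CPM against 3 counts (184-fold, 62.7 to 895). Interferon-gamma genes were higher in 12 of 14 and between in 2 (median 2.26, percentile 100), with Cxcl10 at 114 CPM against 3 counts (97.8-fold, 33.2 to 477). In adventitial fibroblast-like cells the matrix proteoglycan Lum had 4 counts (3.97 CPM) against 217 CPM, 54.6-fold lower (20.8 to 204). AT2-like cells had 4 of 5 type 2 stromal genes higher and 1 between (median 2.55, percentile 100), with Il33 at 2158 against 369 CPM, and 6 of 7 neutrophil-attracting genes higher and 1 between (median 2.77, percentile 100). General capillary endothelium-like cells had 4 of 6 matrix genes higher and 2 between (median 1.92, percentile 100), with Thbs1 at 489 against 38.2 CPM. Their interferon-gamma list had 13 of 21 higher and 8 between (median 1.13, percentile 100), with Serpina3g at 389 against 10.3 CPM, while Esm1 had 5.30 against 75.6. Arterial or venous endothelium-like cells had 4 of 7 adhesion genes higher, 1 lower and 2 between (median 1.44, percentile 100), with Ackr1 at 451 against 27.3 CPM and Selp at 1239 against 135. Retnla and Ccl24 in general capillary endothelium-like cells, at 759.7 and 129 CPM, stood at 7.27% and 4.79% of the library level. Clusters 77 and 93 led fibroblast-like cells after recall against 78 and 73, clusters 109 and 108 led AT2-like cells against 97 and 106, and cluster 13 led the capillary class against 2.

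Recall against no recall under papain+CpG raised the same question after the combined first exposure, with the same open reading of a CpG dose at recall. Neutrophil-like cells were 2.59-fold higher in share (2.26 to 2.98), monocyte or interstitial macrophage-like cells 4.89-fold higher (4.22 to 5.68) and alveolar macrophage-like cells 2.82-fold lower. Unnamed cells, 25.4% of kept cells in papain+CpG recall, lie outside these shares. Counting them as hematopoietic would make both higher folds smaller and the lower fold larger. The interferon-gamma list was above 0 in 12 of 12 classes (median 2.40), and so was the STAT6 list (median 1.36). In alveolar macrophage-like cells 18 of 20 of its genes were at least 2-fold higher and 2 between (median 3.60, percentile 100), with Iigp1 at 92.5 CPM against 0.555, 166-fold higher (96.7 to 314). The STAT6 list had 7 of 11 higher and 4 between (median 1.62, percentile 100), with Arg1 at 178 against 0.641 CPM and Ccl24 at 484 CPM against 0 counts, at least 3780.5-fold higher. Rnase2a, a secreted ribonuclease, had 184 against 0.214 CPM. All 21 measured interferon-gamma genes were higher in monocyte or interstitial macrophage-like cells (median 2.94, percentile 100), with Cxcl9 at 1252 CPM against 22.3, 56.2-fold higher (42.5 to 76.1). Neutrophil-like cells had 19 of 19 higher (median 5.01, percentile 100), with Cxcl10 at 1453 against 6.22 CPM and Gbp5, an interferon-induced GTPase, at 468 CPM against 0 counts, at least 150.4-fold higher. Clusters 7 and 11 led alveolar macrophage-like cells after recall against 10 and 11, cluster 5 led the joined monocyte class against 4, and cluster 25 led the neutrophils against 14.

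In structural and T cells under papain+CpG, fibroblast-like cells had 4 of 8 type 2 stromal genes at least 2-fold higher after recall and 4 between (median 1.18, percentile 100), with Ccl11 at 140.3 against 52.7 CPM and Ccl7 at 135 CPM against 1 count (341-fold, 60.0 to 13556). Their neutrophil-attracting list had 5 of 6 higher and 1 between (median 3.86, percentile 100, and 2.01 without cluster 91), with Saa3 at 312 against 11.1 CPM, and their interferon-gamma list had 18 of 19 higher and 1 between (median 2.46, percentile 100, and 1.98 without cluster 91). General capillary endothelium-like cells had 20 of 22 interferon-gamma genes higher and 2 between (median 1.98, percentile 100), with Cd274, which encodes the inhibitory ligand PD-L1, at 154 against 19.9 CPM. Aerocyte-like capillary cells, 42 against 142, had 4 of 4 MHC class II genes higher (median 2.72, percentile 100), with H2-Ab1 at 171 against 17.6 CPM, which is 10.2% and 2.55% of the library levels. AT2-like cells had 3 of 5 neutrophil-attracting genes higher and 2 between (median 1.47, percentile 100), with Lcn2 at 2689 against 971 CPM. CD8 T-like cells had 9 of 14 type 1 genes higher and 5 between (median 1.15, percentile 100), with Cxcr3 at 105 against 13.9 CPM and the type 1 transcription factor Tbx21 at 59.1 against 9.25. Clusters 81 and 79 led fibroblast-like cells after recall against 74 and 78, clusters 106 and 101 led AT2-like cells against 106 and 97, and cluster 13 led the capillary class against 2. Clusters 47 and 50 led CD8 T-like cells in both at different shares. They held 45.5% and 43.2% after recall and 76.8% and 19.8% without it. The free-RNA tracer list was above 0 in 11 of 12 classes (median 0.63).

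**Figure D3:**
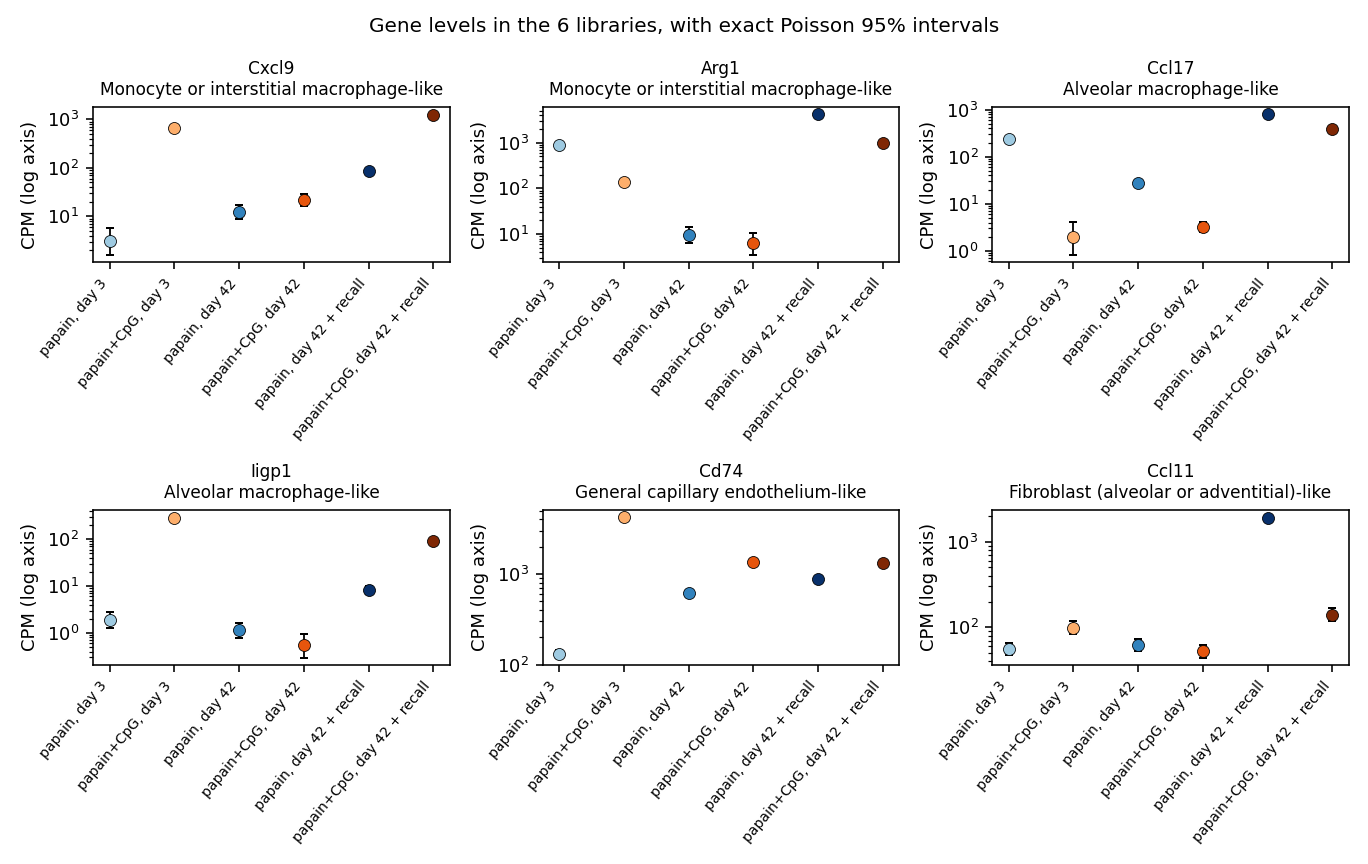
Points give CPM on a log axis for 6 gene and class pairs in the 6 libraries, with exact Poisson 95% intervals. Cxcl9 in monocyte or interstitial macrophage-like cells reaches 1252 CPM in papain+CpG recall against 87.2 in papain recall, and Ccl11 in fibroblast-like cells 140.3 against 1909.5.

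The recall ratios of both regimes were set side by side over the genes measured in both, as the median difference of papain minus papain+CpG. Brackets here hold intervals over the genes of a list. For interferon-gamma genes the difference was −0.98 (−1.60 to −0.20) in alveolar macrophage-like, −2.14 (−2.62 to −1.24) in monocyte or interstitial macrophage-like, −2.13 (−2.67 to −1.62) in neutrophil-like and −1.52 (−2.07 to −1.10) in arterial or venous endothelium-like cells, so these medians of recall were larger under papain+CpG. In fibroblast-like cells it was −0.02 (−0.64, −1.17 to 0.30, in alveolar fibroblast-like cells alone) and in aerocyte-like cells 0.10. For STAT6 response genes it was 0.99 (0.02 to 2.57) in monocyte or interstitial macrophage-like cells and 0.54 in alveolar macrophage-like cells, where the interval covered 0 (−2.59 to 0.91). It was below 0 in classical monocyte-like (−0.13), B-like (−0.34) and NK-like cells (−0.08). For type 2 stromal genes it was 1.19 in fibroblast-like cells, where the interval also covered 0 (−2.06 to 3.53), and −0.20 in alveolar macrophage-like cells. Type I interferon genes in monocyte or interstitial macrophage-like cells differed by −1.99 (−2.46 to −1.74), with 17 of 17 genes larger under papain+CpG. The median of papain+CpG against papain in this class was −1.01 without recall and 1.10 with it. Part of the difference thus lies in the levels without recall, where the make-up of the joined class differed. Chemokines differed by −1.91 (−3.01 to 0.64) in the same class and by 0.96 (0.04 to 2.79) in fibroblast-like cells. In alveolar fibroblast-like cells alone the chemokine difference was −0.53 (−1.59 to 1.44) over 4 genes, opposite in sign to the joined class. Type 1 genes in CD8 T-like cells differed by −0.53 (−1.67 to 0.52), and by 0.01 after centring each gene within libraries. These are differences of ratios between 4 libraries and were not tested. A CpG dose at recall, if given, would enter the papain+CpG ratios.

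**Figure D4:**
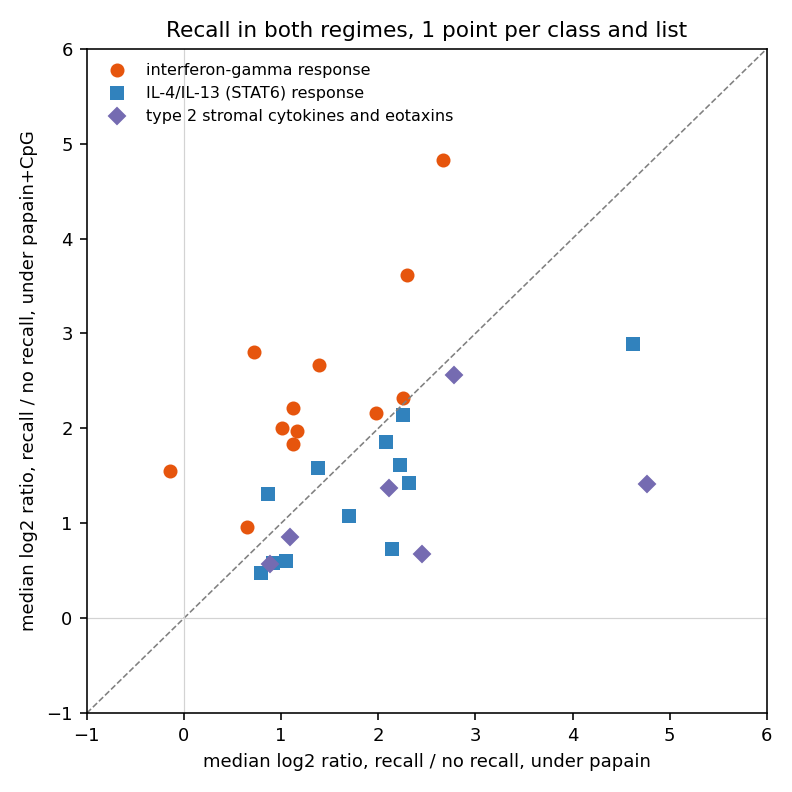
Each point is 1 class and gene list, placed by its median log2 ratio of recall to no recall under papain (horizontal) and under papain+CpG (vertical), over genes measured in both, and the dashed line marks equal values. The interferon-gamma list of neutrophil-like cells lies at 2.67 and 4.83, and the type 2 stromal list of fibroblast-like cells at 4.76 and 1.41.

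The comparison of day 42 without recall with day 3 addressed how each acute state had changed by the later time. Under papain, alveolar macrophage-like cells had 5 of 10 STAT6 genes at least 2-fold lower at day 42 and 5 between (median −0.95, percentile 0), with Chil4 at 4 counts (0.145 CPM) against 90.1 CPM and Ccl17 at 27.6 against 243. Monocyte or interstitial macrophage-like cells had 8 of 13 lower, 1 higher and 4 between (median −2.00, percentile 0), with Arg1 at 9.77 CPM against 888, 90.9-fold lower (63.2 to 136). ILC2-like cells, 101 against 35, had 3 of 11 type 2 effector genes lower, 1 higher and 7 between (median −0.38, percentile 1.75), with the growth factor Csf2 at 111 against 529.5 CPM and Areg higher at 445 against 197. AT2-like cells had 7 of 8 proliferation genes lower and 1 between (median −2.54, percentile 0), with Mki67 at 13.1 against 88.5 CPM. Fibroblast-like cells had 8 of 16 matrix genes lower and 8 between (median −0.93, percentile 0), with Postn at 2.72 against 77.2 CPM and Col1a1, the main chain of type I collagen, at 614 against 1806. Clusters 10 and 9 led alveolar macrophage-like cells at day 42 against 7 and 10, cluster 4 led the joined monocyte class against 8, and clusters 78 and 73 led fibroblast-like cells against 76 and 73. AT2-like cells were led by clusters 97 and 106 at day 42 and by 94 and 95 at day 3.

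Under papain+CpG, the interferon-gamma list was lower at day 42 than at day 3 in 16 of 16 classes. Alveolar macrophage-like cells had 21 of 22 of its genes at least 2-fold lower and 1 between (median −5.04, percentile 0), with Iigp1 at 0.555 CPM against 284, 512-fold lower (298 to 965). General capillary endothelium-like cells had 22 of 22 lower (median −2.91, percentile 0), with Cxcl10 at 6.45 against 529 CPM. Their MHC class II list had 5 of 7 lower and 2 between (median −1.24, percentile 0.01), with Cd74 at 1349.9 against 4223 CPM. Under papain alone Cd74 was higher at day 42 than at day 3 in that class, at 622 against 132 CPM, with a list median of 1.67. Different clusters led the class there, with 58.7% in cluster 2 at day 42 and 84.9% in cluster 12 at day 3. Monocyte or interstitial macrophage-like cells had 8 of 9 chemokines lower and 1 higher (median −3.36, percentile 0), with Ccl5 at 36.8 CPM against 4646, 126-fold lower (102 to 159). Cluster 10 led alveolar macrophage-like cells at day 42 against cluster 41, cluster 2 led the capillary class against 1, and cluster 4 led the joined monocyte class against 38 and 40. The free-RNA tracer list was below 0 in 14 of 16 classes between these libraries (median −1.52) and in 16 of 18 under papain (median −0.92).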

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

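Tests of Fbp1, of the free RNA of single genes and of a repeated CpG dose were chosen only after the result was seen, and those of free RNA and depth for the interferon-gamma list at recall before it. The gene lists below had medians of opposite sign in related comparisons. Each value is a median log2 ratio between single libraries, and the differences between comparisons were not tested.

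For papain+CpG against papain, the MHC class II list of fibroblast-like cells had 2.57 at day 3, −0.87 at day 42 without recall and 1.01 with recall. The type I interferon list of monocyte or interstitial macrophage-like cells had 3.48, −1.01 (−0.44 in classical monocyte-like cells alone) and 1.10 at those times, and that of neutrophil-like cells 3.06, −0.78 and 0.90. In fibroblast-like cells the type 2 stromal list had 0.83 at day 3 and −1.16 with recall, and the chemokine list 4.47 and −0.90.

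For recall against no recall, the MHC class II list of classical monocyte-like cells had −0.73 under papain and 0.66 under papain+CpG, and the type I interferon list of monocyte or interstitial macrophage-like cells −0.67 and 1.5. For day 42 against day 3, the type I interferon list had 0.76 under papain and −2.73 under papain+CpG in aerocyte-like capillary cells, 1.10 and −2.14 in classical monocyte-like, 1.60 and −2.64 in monocyte or interstitial macrophage-like, and 0.83 and −2.82 in neutrophil-like cells. The MHC class II list had 0.96 and −2.42 in fibroblast-like, 1.67 and −1.24 in general capillary endothelium-like, and −0.67 and 0.82 in neutrophil-like cells. The interferon-gamma list of gamma-delta T-like cells had 0.88 and −2.49. Cells of unnamed clusters, which no comparison uses, were 25.4% of kept cells in papain+CpG recall.

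Fbp1 in alveolar macrophage-like cells had 34.7 CPM under papain at day 42, from 112 of 2466 cells, and 0 UMIs in 1903 cells under papain+CpG. The tables argue against free RNA, since the level was 187% of the whole library's, against depth, since 813 UMIs would be expected at the papain level, and against cells of another class, whose highest level was 7.48 CPM. Cluster 7, with 697 of the 957 UMIs, held 72 cells of papain and 9 of papain+CpG. A different mix of clusters is argued against as the whole source, since the papain share of such cells in each cluster would give 40 cells with Fbp1 under papain+CpG, 33.7 of them outside cluster 7. A lower share of a subset finer than the clusters was not tested. Differences between animals or preparations unrelated to CpG cannot be told apart from an effect of CpG with 1 library per group. A lasting effect of CpG on these cells may be tested in replicates.

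Retnla and Ccl24 in lymphocyte-like, neutrophil-like, nonclassical monocyte-like and general capillary endothelium-like cells at papain recall were set against the share of library level that Sftpc, an alveolar epithelial transcript, reached there. The median ratio over 7 classes and both genes was 1.67, so free RNA is a candidate source of their signal. Ccl24 stood apart at 5.43 in B-like and 5.20 in neutrophil-like cells, but at 2.77 and 1.92 times the share of Scgb1a1, an airway transcript, so the reading for these pairs depends on the tracer and stays open. For Cxcl9 and Cxcl10 in capillary endothelium at papain+CpG day 3 the lowest such ratio was 9.83, and 3.15 against Scgb1a1, which argues against free RNA as the source.

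The interferon-gamma list was higher in papain+CpG recall than in papain recall in 11 of 12 classes (median over classes 1.06). With free RNA subtracted the median was 1.04, and with cells thinned to 1 depth it was 0.82 over 10 classes, which argues against both as the whole source. A CpG dose at recall, as the sample label can be read, cannot be told apart from a lasting effect of the first exposure, since there is 1 library of papain+CpG with recall.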

How the results depend on the processing

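Leaving out clusters 91 and 108 and counting unnamed cells as hematopoietic were chosen only after the result was seen, and the other alternatives were planned. No paired analysis was possible because all groups carry replicate number 1 and no result comes from a test. The papain+CpG recall library held the fewest UMIs (28663717) and kept cells (2145) of the 6, while its median of 5642 UMIs per kept cell was the highest. Values are log2 ratios. "Moved" means outside the counting or list interval, and the cause was not tested for any value below. List intervals run over the genes of a list and can be wide. That of STAT6 in alveolar macrophage-like cells at day 3 was −6.71 to −0.14. That of the type 2 stromal recall difference in fibroblast-like cells was −2.06 to 3.53. Staying within such an interval is therefore a weak check. Of 342 gene results, 2637 of 3039 values under alternatives stayed within the interval, 393 moved and 9 reversed. Thinning cells alone moved 188 and reversed 4, with 138 within the interval, so most gene values depended on that setting, while the stricter cell filters moved 0. For 70 list medians these counts were 750, 6 and 1 of 757, for 16 recall differences 122, 1 and 10 of 133, and for 24 shares 137, 28 and 1 of 166. Counting unnamed cells as hematopoietic moved 5 shares and reversed 1, with 18 within the interval. Alternatives that left a list or class below its minimum gave no value.

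Among main results, the monocyte or interstitial macrophage share at day 3 (2.32) was 2.64 with doublets kept, 3.78 with each gene centred and 2.79 of all kept cells. The neutrophil share at papain recall (1.40) was 1.01 of all kept cells. The other 10 stayed within their intervals: ILC2 share at day 42 −2.01 to −1.77, STAT6 in alveolar macrophages −2.14 to −1.35 at day 3 and −1.06 to −0.92 at recall, interferon-gamma in capillary cells 3.06 to 3.25 at day 3 and −3.0 to −2.68 for day 42 against day 3, MHC class II there 0.49 to 0.67 at day 42, interferon-gamma in the joined monocyte class 1.79 to 1.87 and type 2 stromal genes in fibroblasts −1.70 to −1.15 at recall, and the recall differences −0.99 to −0.76 (interferon-gamma, alveolar macrophages) and 1.15 to 1.41 (type 2 stromal, fibroblasts).

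Reversed values were the joined monocyte share at CpG recall (0.42), −0.07 with unnamed cells counted, and the CD4 type 1 list at day 42 (0.99), −0.05 with doublets kept. Recall differences reversed for neutrophil-attracting genes in AT2-like cells (0.14), −0.06 with doublets kept, −0.34 at lower resolution and −0.20 without mitochondrial, ribosomal and hemoglobin genes. They reversed for type 1 genes in CD8 T-like cells (−0.53), 0.01 centred and 0.04 thinned, and for interferon-gamma genes in fibroblast-like cells (−0.02), 0.16 with doublets kept, 0.45 at lower resolution, 0.00 with TMM, 0.05 thinned and 0.48 without the 2 clusters. Genes reversed with doublets kept were Ccl4 (−0.52) and Ccl5 (−0.05) in CD4 T-like cells at day 42, Ccl24 in AT2-like cells at CpG recall (−2.30) and Retnla in alveolar macrophage-like cells at papain+CpG recall (−0.23). Thinned, they were Tnf in alveolar macrophage-like (−0.26), Grem1 in adventitial fibroblast-like (0.45) and Hlf in CD4 T-like cells (0.04) at day 42, and Hist1h1b in CD4 T-like cells at papain recall (0.22). Retnla in alveolar macrophage-like cells at papain recall was −5.62 with free RNA subtracted.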

Other observations

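The genes and classes in this part were chosen after their values were seen. Mesothelium-like cells, 75 in papain+CpG day 3 and 55 in papain day 3, had 13 of 13 measured proliferation genes at least 2-fold higher with CpG (median log2 ratio 4.44, percentile 100), opposite in sign to AT2-like cells at −4.27. Mki67, a nuclear protein of cycling cells, had 81.7 CPM (66.7 to 99.0) in these cells with CpG and 1 count without it, and Top2a, a topoisomerase of dividing cells, had 125 (106 to 146) against 1 count. With CpG the UMIs of Mki67 lay in 17 of 75 cells (22.7%) and those of Top2a in 19 (25.3%). Each was held by 2.17% of B-like cells at lower depth (medians of 2004 and 16615 UMIs). Both were low in mesothelium-like cells of the later libraries, with Mki67 at 1 count in papain day 42, 1 in papain+CpG day 42 and 4 in papain recall. Their Cd74 level was 3327 CPM (3227 to 3429) with CpG against 62.8 (47.4 to 81.5), and H2-Ab1 had 874 against 15.7. Cluster 90 held 98.7% of the mesothelium-like cells of papain+CpG day 3, and cluster 84 led in papain day 3. In AT2-like cells Top2a was likewise lower with CpG at day 3, at 4.95 CPM against 70.2.

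Glycolysis and hypoxia genes were above 0 with CpG at day 3 in 13 of 15 classes (median 0.48), up to 1.03 in general capillary endothelium-like cells, and below 0 in 14 of 16 for day 42 against day 3 under papain+CpG (median −0.71). Immediate early and dissociation response genes, which can mark tissue handling, were above 0 with CpG at day 3 in 10 of 15 classes (median 0.18), at day 42 without recall in 9 of 18 (median 0.01) and with recall in 10 of 12 (median 0.12, up to 1.08 in AT2-like cells). In B-like cells at day 3, 2 of 4 immunoglobulin constant region genes were at least 2-fold lower with CpG, 1 higher and 1 between (median −0.83, percentile 0.45), and 24.3% of these cells with CpG against 0.559% without it lay in cluster 36, whose median was 704.5 UMIs. The mucous and goblet list could be read in alveolar macrophage-like cells at day 3, where 4 of 4 measured genes, which include Retnla and Chil4, were lower with CpG (median −5.48, percentile 0), and in no other class of that comparison were 4 members measured.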
